A study of Arabidopsis thaliana with 12 samples.

How the data were processed

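Total RNA of 4-week-old seedlings, labelled with Cy3 per the labels, was hybridised to 12 one-colour arrays of Agilent design 021169, 1 array per sample in 4 groups of 3. Per the labels, the replicates are independent experiments on different plants. The p-values therefore measure the spread between such experiments, pooled over the 4 groups. Groups, the 150 mM NaCl dose and the 3 h time were taken from the labels.

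The signal intensities were made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, which subtracted background, detrended spots within each array and applied no normalization between arrays. The flags of the same software (other values, 1 for yes and 0 for no) mark, per the file headers, spots well above background, saturated or uneven. The authors also deposited a table of log2 values, which its equal column distributions show to be quantile normalized over all probes; the lowest correlation of a column with its own array was r = 0.998, and 0 columns lacked a sample. The main comparisons used the processed intensities, and the authors' table served as an alternative.

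Of 43603 probes, 38 were left out because their only spot was marked uneven, and 43565 were used. 36832 probes were matched to 1 gene, 24658 by locus code, 11521 by transcript accession, 513 by symbol and 140 by synonym, while 6287 had no locus and 484 several. Gene symbols came from the reference table of the TAIR10.1 annotation; a genome sequence and promoter motifs were not used here. Log2 signals were centred on the 75th percentile of each array. A gene was tested if a probe was well above background on all 3 arrays of at least 1 group, with its brightest such probe, which left 20406 genes. Of 2360 called genes with several probes in the water comparison, 232 (9.83%) had a probe of opposite sign. A gene dim on every array of a group is given as a lower bound against the dimmest signal well above background on each array. A gene dim on only some arrays of a group is given as fitted. Such a size, as for DFR, UGT79B1, AAE12 and PUB19, can rest partly on values near background.

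Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 12 arrays with 1 mean per group. Genes were called at an adjusted p under 0.05, with Benjamini-Hochberg adjustment over all genes tested in each of 5 comparisons: overexpressor against mutant in water and in salt, salt against water in each genotype, and the interaction. The median within-group SD was 0.334 (overexpressor, water), 0.165 (mutant, water), 0.193 (overexpressor, salt) and 0.259 (mutant, salt), and the number of arrays limits the precision. Overlaps of calls were tested with Fisher's exact test. Pictures were drawn with matplotlib 3.10.9 in Python 3.11.15.

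Before the data were examined, 25 lists with 531 members were fixed, covering stress regulators, hormones, metabolism, transport and markers of other tissues. They were tested with camera at its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Of 125 list tests 47 were called, and 0 with an estimated correlation. In 12 list tests the median, mean and test differed in sign, 0 of them called: proline metabolism in water; superoxide dismutases and raffinose in salt; ABA metabolism, jasmonate, salicylate and flavonoid genes for salt in the mutant; and proline, ion transport, clock, root and seed storage genes in the interaction. The genes named were set by a rule fixed at the same time. It takes bHLH112 always; the 6 largest called increases and decreases with a symbol whose groups do not overlap; up to 3 called members with the largest change from each list with at least 3 called; and all proline genes and superoxide dismutases. The interaction needs no separation of groups. Outside the rule, and chosen after their values were seen, are GRX480, SEP2 and AP3 in water, PAP1, SUS3, UGT74B1 and CYP79B3 for salt in the overexpressor, XTH22 and XTH18 for salt in the mutant, and CYP707A3 and MYB51 in the interaction; other such genes are marked where they stand.

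The alternatives were quantile normalization, normexp background correction with an offset of 50, a percentile over detected probes, the authors' table, no or a stricter filter, the mean of a gene's probes, a variance trend, only the arrays compared, slide or replicate number as a block, and leaving out each array. Data were simulated with the same group sizes, with independent genes, the same SD of a gene in all groups and no slide effect. There 46.3%, 76.1% and 97% of genes changed 2-, 4- and 16-fold were recovered for the water comparison. For the interaction 22.4%, 59.7% and 89.4% were recovered. Of the calls in these 2 comparisons 9.32% and 7.32% were false. In the data genotype is confounded with slide and the spread differs between groups, so these shares need not hold there.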

Results

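Whole Arabidopsis thaliana seedlings, roots and shoots pooled, were profiled at 4 weeks of age on 12 one-colour Agilent arrays. The plants either overexpressed bHLH112 (AT1G61660), a basic helix-loop-helix transcription factor, or carried a SALK T-DNA insertion in that gene. Each genotype received water or 150 mM NaCl for 3 h, which gave 4 groups of 3 arrays, each array from different plants. The title of the series places the question in how this factor regulates genes under abiotic stress. No wild type was analysed here, so a difference between the genotypes does not show which of them departed from wild type. Between 68.3% and 76.4% of the probes on an array were well above background. The 75th percentile of the processed signal ranged from 1100 to 2484, and 0 probes were saturated. Replicates correlated across genes with Pearson r from 0.923 to 0.983, and genes are not independent replicates. In the overexpressor in water, replicate 2 stood apart, with r = 0.923 and 0.938 against the others. In the mutant in salt, replicate 1 stood apart, with r = 0.948 and 0.956. The first principal component held 49.2% of the variance and set every mutant array (18.3 to 79.1) above every overexpressor array (-123 to 5.02). Signal was confounded with genotype: that percentile was 1100 to 1931 on overexpressor arrays and 1903 to 2484 on mutant arrays. Overexpressor water replicates 3 and 1, lowest on the component, were dimmest (1100 and 1360), and mutant salt replicate 2, highest on it, was brightest (2484). The component therefore does not separate genotype from signal. The arrays lay on 3 slides of 4. Slide 1 held the overexpressor in water and its salt replicate 1. Slide 2 held the overexpressor in salt replicates 2 and 3 and the mutant in water replicates 1 and 2. Slide 3 held the mutant in water replicate 3 and the mutant in salt. No slide held both groups of either comparison between genotypes.

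The bHLH112 transcript was higher in the overexpressor under both treatments on its brightest probe. On the log2 scale, relative to the array's 75th percentile, the group means in water were 0.65 ± 0.26 (SD, n = 3) in the overexpressor and -2.72 ± 0.077 (SD, n = 3) in the mutant. They differed by 3.37 (SE 0.19, limma adjusted p = 7.2e-05). Under salt the means were 1.3 ± 0.13 and -2.26 ± 0.35 (SD, n = 3 each), a difference of 3.56 (SE 0.19, adjusted p = 4.6e-05). The salt differences of this transcript, 0.66 in the overexpressor and 0.46 in the mutant, did not pass the test (adjusted p = 0.096 and 0.37). The probe, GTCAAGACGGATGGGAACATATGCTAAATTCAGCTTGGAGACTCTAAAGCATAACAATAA, lies on chromosome 1 from 22757586 to 22757645 in the ath1:Jan2004 build named in the file headers. A dimmer probe, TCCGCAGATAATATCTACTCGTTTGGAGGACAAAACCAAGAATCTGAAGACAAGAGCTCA, is placed from 22758869 to 22759024. Its 60 bases cover 156 bases of the genome, so it lies across a splice junction. On that probe the genotypes differed by 1.82 under salt (SE 0.32, adjusted p = 0.012 over all probes). In water they differed by 0.25 (SE 0.32, adjusted p = 0.58). Both probes were well above background on all 12 arrays, the mutant's included. Where the insertion lies relative to them is not given in the sources used here, so the mutant's remaining signal does not check the loss of the transcript. With slide as a block the differences on the brightest probe were 3.56 in water and 3.7 in salt (adjusted p = 0.054 and 0.093; over the other alternatives 3.9e-05 to 0.0042 and 3.5e-05 to 0.0057), in a fit with 6 residual degrees of freedom. The mean of all bHLH112 probes gave 1.81 in water and 2.69 in salt.

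**Figure D1:**
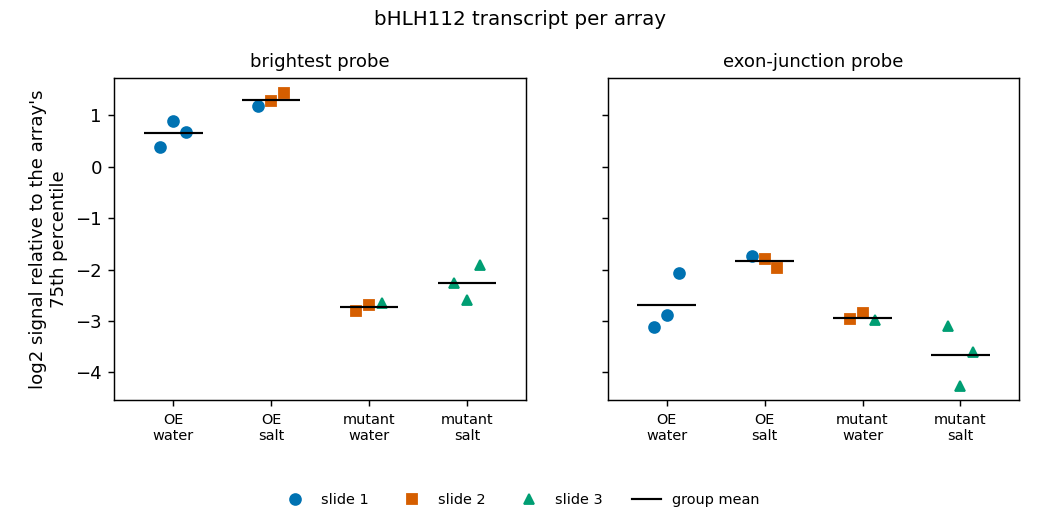
Log2 processed signal of both bHLH112 probes, relative to the 75th percentile of the array, by group; each point is 1 array, its shape and colour give the slide, and lines are group means. On the brightest probe the overexpressor arrays lie between 0.37 and 1.44 and the mutant arrays between -2.81 and -1.91, while on the exon-junction probe the water groups overlap, at -3.11 to -2.06 and -2.99 to -2.84.

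In water, transcripts of most listed flavonoid genes were lower in the overexpressor than in the mutant. Phenylpropanoid and flavonoid genes were 0 higher, 17 lower and 3 not called of 20, with 0 higher and 17 lower adjusted over the list alone and a median of -2.59 (adjusted p = 7.6e-07, but adjusted p = 0.67 with an estimated correlation). DFR, the reductase that leads into anthocyanins, differed by -6.35 (SE 1.4, adjusted p = 0.0093). The anthocyanin glycosyltransferase gene UGT79B1 differed by -5.46 (SE 1.1, adjusted p = 0.008). In the overexpressor in water, replicates 1 to 3 lay at -8.48, -3.63 and -7.56 for DFR and at -8.02, -4.59 and -8.34 for UGT79B1. Both sizes therefore rest partly on values near background. TT19, a glutathione transferase of anthocyanin accumulation, differed by -5.35 (SE 1.3, adjusted p = 0.015), but a dimmer probe of it gave 0.645, the opposite sign. Floral organ markers moved with this comparison. They were 0 higher, 2 lower and 11 not called of 13, with 0 higher and 0 lower adjusted over the list alone and a median of -1.36 (adjusted p = 0.047, but adjusted p = 0.79 with an estimated correlation), or -1.06 with dim genes at their bound. SEP2 and AP3, floral organ identity genes, were the called members, at least 12.6-fold and 12.8-fold lower. Each "at least" fold sets the bright group against the array's dimmest signal well above background, because the other group was not well above background on any array. The floral call ended under quantile normalization (-1.19, adjusted p = 0.057), with slide as a block (0.178, adjusted p = 0.96), without overexpressor water replicate 1 (-1.55, adjusted p = 0.053), without overexpressor water replicate 2 (-1.65, adjusted p = 0.15), without overexpressor water replicate 3 (-1.42, adjusted p = 0.055), without mutant water replicate 2 (-1.59, adjusted p = 0.053), without mutant water replicate 3 (-1.06, adjusted p = 0.11) and without overexpressor salt replicate 3 (-1.36, adjusted p = 0.053). Across all genes 7524 of 20406 were called, 3764 higher and 3760 lower in the overexpressor, and 3884 of them differed at least 2-fold (1475 higher and 2409 lower). In 9639 of the 20406 genes tested the groups did not overlap, where chance gives 10%.

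Among stress transcription factors in water, more were called lower than higher in the overexpressor: 3 higher, 14 lower and 11 not called of 28, with 3 higher and 14 lower adjusted over the list alone and a median of -1.16 (adjusted p = 0.0041, but adjusted p = 0.67 with an estimated correlation). DDF1, an AP2/ERF factor of the CBF family, was at least 51.8-fold lower (adjusted p = 0.0012). CBF1 and CBF2, which drive the cold response, differed by -3.93 and -3.63 (adjusted p = 0.0085 and 0.0089). The largest decreases included RRTF1, a redox-responsive ERF factor, at least 391-fold lower, and DDF2, at least 19.9-fold lower (adjusted p = 0.0021 and 0.0016). They also included ORA47, an AP2/ERF regulator of jasmonate synthesis, at -6.52 (SE 0.76, adjusted p = 0.00096), and AAE12 at -6.06 (adjusted p = 0.0031). Ethylene genes were 2 higher, 10 lower and 7 not called of 19, with 2 higher and 10 lower adjusted over the list alone and a median of -1.25 (adjusted p = 0.016, but adjusted p = 0.67 with an estimated correlation). ERF6, the ethylene-synthesis gene ACS6, and ERF105 differed by -3.7, -3.6 and -3.4 (adjusted p = 0.00055, 0.00066 and 0.0032). Jasmonate genes were 2 higher, 13 lower and 9 not called of 24, with 2 higher and 13 lower adjusted over the list alone and a median of -1.22 (adjusted p = 0.0055, but adjusted p = 0.67 with an estimated correlation). The vegetative storage proteins VSP1 and VSP2 differed by -5.12 and -5.11 (adjusted p = 0.0092 and 0.0081), whereas the defensin PDF1.2A was higher by 4.5 (SE 1.3, adjusted p = 0.022). Glucosinolate genes were 1 higher, 9 lower and 9 not called of 19, with 1 higher and 9 lower adjusted over the list alone and a median of -0.77 (adjusted p = 0.0055, but adjusted p = 0.67 with an estimated correlation). MYB29, a regulator of aliphatic glucosinolates, and FMOGS-OX1 differed by -1.59 and -1.21, and MAM3 by 1.2 (adjusted p = 0.012, 0.035 and 0.042). The stress factor call ended without overexpressor water replicate 2 (-1.15, adjusted p = 0.12), the ethylene call without overexpressor water replicate 2 (-1.44, adjusted p = 0.14) and the jasmonate call without overexpressor water replicate 2 (-1.1, adjusted p = 0.1).

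Salicylate and pathogen defence genes were higher in the overexpressor in water: 7 higher, 1 lower and 9 not called of 17, with 8 higher and 1 lower adjusted over the list alone and a median of 0.75 (adjusted p = 0.0055, but adjusted p = 0.72 with an estimated correlation). ALD1 and FMO1, enzymes of systemic acquired resistance, differed by 5.13 and 4.88, and PAD3, of camalexin synthesis, by 4.21 (adjusted p = 0.014, 0.0075 and 0.005). The member called lower was the glutaredoxin gene GRX480 at -1.78. Also among the largest increases were CYP71A13, of camalexin synthesis, the patatin-like phospholipase gene PLA2A and the beta-1,3-glucanase gene BG3, at 5.59, 4.55 and 4.44 (adjusted p = 0.012, 6e-04 and 6e-04). Senescence genes were 8 higher, 1 lower and 2 not called of 11, with 10 higher and 1 lower adjusted over the list alone and a median of 1.26 (adjusted p = 0.0033, but adjusted p = 0.67 with an estimated correlation). SAG13, ORE1, a NAC regulator of leaf senescence, and SEN1 differed by 3.97, 3.58 and 3.16 (adjusted p = 0.0066, 9e-04 and 0.0061). Circadian clock genes were 6 higher, 2 lower and 10 not called of 18, with 7 higher and 2 lower adjusted over the list alone and a median of 0.41 (adjusted p = 0.04, but adjusted p = 0.67 with an estimated correlation). The clock genes PRR5, GI and PRR7 differed by 3.43, 1.44 and 1.21 (adjusted p = 7.2e-05, 0.00096 and 0.0034). Photosynthesis genes, used as markers of green tissue, were 0 higher, 0 lower and 29 not called of 29, with 0 higher and 0 lower adjusted over the list alone and a median of 0.33 (adjusted p = 0.011, but adjusted p = 0.83 with an estimated correlation). The salicylate call ended with slide as a block (0.67, adjusted p = 0.069) and without overexpressor water replicate 2 (0.599, adjusted p = 0.1). The clock call ended with slide as a block (0.457, adjusted p = 0.093), without overexpressor water replicate 1 (0.225, adjusted p = 0.089) and without mutant water replicate 3 (0.474, adjusted p = 0.067), and the photosynthesis call under quantile normalization (0.0244, adjusted p = 0.9), with slide as a block (-0.0261, adjusted p = 0.52), without overexpressor water replicate 1 (0.318, adjusted p = 0.053) and without overexpressor water replicate 3 (0.178, adjusted p = 0.17).

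ABA metabolism and signalling genes went both ways in water: 10 higher, 4 lower and 13 not called of 27, with 10 higher and 4 lower adjusted over the list alone and a median of 0.015 (adjusted p = 0.3). The ABA receptor genes PYL6 and PYL5 were higher by 4.4 and 2.98, and CYP707A3, a hydroxylase that degrades ABA, differed by -3.38 (adjusted p = 0.0029, 0.00045 and 0.00085). Ion transport genes were 7 higher, 2 lower and 12 not called of 21, with 7 higher and 2 lower adjusted over the list alone and a median of 0.45 (adjusted p = 0.11). The exchanger genes CHX17 and CAX3 and SOS3, the calcium sensor of the salt overly sensitive pathway, differed by 2.99, 2.54 and 1.86 (adjusted p = 0.027, 0.018 and 0.0052). Proline metabolism genes were 2 higher, 2 lower and 6 not called of 10, with 2 higher and 3 lower adjusted over the list alone. P5CS1, the stress-induced first enzyme of proline synthesis, differed by -2.5 (SE 0.47, adjusted p = 0.0053) and P5CDH by -0.53 (adjusted p = 0.0072). PRODH2 and OAT were higher by 1.04 and 0.98 (adjusted p = 0.01 and 0.022). The proline genes P5CS2, P5CR, PRODH1, PROT1, PROT2 and PROT3 were not called (-0.54 to 1.11). Superoxide dismutase and ascorbate-glutathione genes were 3 higher, 4 lower and 17 not called of 24, with 3 higher and 4 lower adjusted over the list alone. CAT1, a catalase, DHAR1 and the plastid superoxide dismutase FSD3 differed by 1.83, -1.4 and -1.1 (adjusted p = 0.0067, 0.025 and 0.031). The superoxide dismutases CSD1, CSD2, CSD3, FSD1, FSD2 and MSD1 were not called (-1.06 to 1.25).

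Members of further lists differed in water as well, but none of these lists was called by camera (adjusted p = 0.11 to 0.53). Across all genes 7524 of 20406 were called, so such counts alone do not set these lists apart. Auxin response genes were 3 higher, 7 lower and 9 not called of 19, with 3 higher and 7 lower adjusted over the list alone; GH3.1, of auxin conjugation, was at least 2.7-fold lower, and IAA30 and IAA6 differed by -2.77 and -2.03. Expansins and XTHs, enzymes of the cell wall, were 2 higher, 6 lower and 11 not called of 19, with 3 higher and 7 lower adjusted over the list alone. XTH17 was at least 5.45-fold lower, and XTH22 and XTH25 differed by -2.83 and 2.96. Iron deficiency genes were 3 higher, 5 lower and 7 not called of 15, with 4 higher and 5 lower adjusted over the list alone. The iron-uptake peptide genes IMA1 and IMA2 and the nicotianamine synthase gene NAS4 differed by -3.61, -2.61 and -2.38. Class III peroxidases were 4 higher, 5 lower and 36 not called of 45, with 0 higher and 1 lower adjusted over the list alone: PRX40 was at least 8.63-fold lower, and PRX43 and PRX21 differed by -1.66 and 1.99. Heat shock and protein folding genes were 4 higher, 2 lower and 9 not called of 15, with 4 higher and 2 lower adjusted over the list alone: BIP3, HSFA7A and HSP18.2 differed by 3.4, 2.27 and -2.27. Raffinose, starch and sucrose genes were 1 higher, 3 lower and 8 not called of 12, with 1 higher and 4 lower adjusted over the list alone; the beta-amylase gene BAM5 and the galactinol synthase gene GOLS1 differed by -4.99 and -1.84. With slide as a block limma called 1 gene between genotypes in water, AT3G51400, named after its value was seen (4.29, adjusted p = 0.0035), against 2956 genes at an unadjusted p under 0.05, and 99.4% of the 7524 calls had the same direction. The count of 7524 became 4230 without overexpressor water replicate 1, 2924 without overexpressor water replicate 3, 3496 without mutant water replicate 1, 4309 without mutant water replicate 2 and 4579 without mutant water replicate 3.

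Under salt the same kinds of stress regulators were higher in the overexpressor than in the mutant, the opposite of water. Stress transcription factors were 18 higher, 0 lower and 10 not called of 28, with 23 higher and 0 lower adjusted over the list alone and a median of 2.51 (adjusted p = 2.7e-14, but adjusted p = 0.24 with an estimated correlation). DDF1, CBF1 and the zinc finger gene ZAT7 were higher by 5.48, 4.45 and 4.21 (SE 0.77, 0.84 and 0.68; adjusted p = 0.0032, 0.01 and 0.0056). RRTF1 was higher by 5.73 (SE 1.4, adjusted p = 0.022). Ethylene genes were 10 higher, 0 lower and 9 not called of 19, with 12 higher and 0 lower adjusted over the list alone and a median of 1.98 (adjusted p = 4.7e-09, but adjusted p = 0.24 with an estimated correlation). ERF105, ERF6 and ERF104 differed by 3.86, 3.83 and 3.58 (adjusted p = 0.0038, 0.00061 and 0.0019). The defensins PDF1.2A, PDF1.2c, PDF1.2b and PDF1.3 had the largest increases among the named genes, 7.03, 6.91, 6.75 and 6.67 (adjusted p = 0.008, 0.0048, 0.0066 and 0.0046). In all 3835 of 20406 genes were called, 1802 higher and 2033 lower, 1714 of them at least 2-fold (1059 higher and 655 lower). The groups did not overlap in 8910 of all genes tested, where chance gives 10%. The median of all genes was -0.103 here and -0.15 with the percentile taken over probes detected on every array, so small differences stand relative to that shift. The fit with slide as a block called, by limma, 0 genes and 1578 had an unadjusted p under 0.05, with 99.9% of the calls in the same direction. The count of 3835 became 6339 without overexpressor water replicate 2, 1108 without overexpressor salt replicate 1, 783 without overexpressor salt replicate 2, 1014 without mutant salt replicate 2 and 2544 without mutant salt replicate 3.

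Defence and senescence genes were also higher in the overexpressor than in the mutant under salt. Salicylate and pathogen defence genes were 8 higher, 0 lower and 9 not called of 17, with 11 higher and 0 lower adjusted over the list alone and a median of 1.74 (adjusted p = 3.5e-07, but adjusted p = 0.38 with an estimated correlation). The pathogenesis-related genes PR5 and PR2 and SARD1, a regulator of salicylate synthesis, differed by 2.77, 2.64 and 2.68 (adjusted p = 0.0061, 0.011 and 0.014). Senescence genes were 8 higher, 0 lower and 3 not called of 11, with 8 higher and 0 lower adjusted over the list alone and a median of 1.62 (adjusted p = 0.00012, but adjusted p = 0.38 with an estimated correlation). SAG13, ORE1 and SEN1 differed by 2.98, 2.37 and 2.14 (adjusted p = 0.031, 0.007 and 0.04). Flavonoid genes were 0 higher, 7 lower and 13 not called of 20, with 0 higher and 10 lower adjusted over the list alone and a median of -1.7 (adjusted p = 0.00013, but adjusted p = 0.4 with an estimated correlation). ANS, anthocyanidin synthase, CHS, chalcone synthase, and UGT75C1 differed by -3.85, -2.19 and -2.15 (adjusted p = 0.037, 0.00088 and 0.0065). Clock genes were 4 higher, 2 lower and 12 not called of 18, with 7 higher and 2 lower adjusted over the list alone and a median of 0.48 (adjusted p = 0.0049, but adjusted p = 0.38 with an estimated correlation). PRR5, GI and LHY differed by 3.22, 1.2 and -0.92 (adjusted p = 9.9e-05, 0.0033 and 0.0039). ABA metabolism and signalling genes were 9 higher, 0 lower and 18 not called of 27, with 9 higher and 0 lower adjusted over the list alone and a median of 0.49 (adjusted p = 0.00025, but adjusted p = 0.36 with an estimated correlation). CYP707A3, PYL5 and the kinase gene SNRK2.3 differed by 4.07, 1.74 and 1.22 (adjusted p = 6e-04, 0.0042 and 0.0068). Jasmonate genes were 5 higher, 0 lower and 19 not called of 24, with 6 higher and 0 lower adjusted over the list alone and a median of 0.39 (adjusted p = 0.016, but adjusted p = 0.7 with an estimated correlation), among them ORA59 and JAZ8 at 3.35 and 2.56 (adjusted p = 0.03 and 0.045). The jasmonate call under salt ended with slide as a block (-0.0423, adjusted p = 0.88), without overexpressor salt replicate 1 (0.265, adjusted p = 0.059) and without mutant salt replicate 3 (0.0875, adjusted p = 0.24). Ion transport genes were 3 higher, 0 lower and 18 not called of 21, with 2 higher and 0 lower adjusted over the list alone and a median of 0.19 (adjusted p = 0.025, but adjusted p = 0.36 with an estimated correlation). CAX3, the chloride channel gene CLC-C and the sodium exporter gene SOS1 were the called members, at 2.65, 0.6 and 0.39 (adjusted p = 0.025, 0.015 and 0.047). That ion transport call ended with slide as a block (0.307, adjusted p = 0.06), without overexpressor salt replicate 3 (0.0762, adjusted p = 0.073) and without mutant salt replicate 2 (0.0557, adjusted p = 0.077).

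Proline genes under salt were 2 higher, 0 lower and 8 not called of 10, with 2 higher and 0 lower adjusted over the list alone. PRODH2 and OAT differed by 0.97 and 0.91 (adjusted p = 0.022 and 0.044), and P5CS1 by 0.083 (SE 0.47, adjusted p = 0.92), which was not called. Superoxide dismutase and ascorbate-glutathione genes were 1 higher, 2 lower and 21 not called of 24, with 1 higher and 2 lower adjusted over the list alone: FSD3, CAT3 and MDAR6 differed by -1.2, 0.73 and -0.8 (adjusted p = 0.037, 0.02 and 0.021). The superoxide dismutases CSD1, CSD2, CSD3, FSD1, FSD2 and MSD1 were not called (-1.02 to 0.78). Glucosinolate genes were 2 higher, 2 lower and 15 not called of 19, with 2 higher and 2 lower adjusted over the list alone, and included MYB51, a regulator of indole glucosinolates, MAM3 and MYB34 at 2.59, 1.67 and -1.39. In the cell wall list, 2 higher, 3 lower and 14 not called of 19 with 3 higher and 4 lower adjusted over the list alone, XTH22, XTH18 and EXPA5 differed by 3.76, 2.48 and -1.62. Iron deficiency genes were 1 higher, 2 lower and 12 not called of 15, with 1 higher and 2 lower adjusted over the list alone; IMA1, IMA2 and the ferric reductase gene FRO2 differed by -3.37, -2.45 and 1.33. The large decreases outside the lists were DIN2, MIR319b, SOFL2 and ACS4 at -3.19, -2.82, -2.47 and -2.38 (adjusted p = 0.037, 0.042, 0.00067 and 0.016) and GA2OX7, a gibberellin-inactivating oxidase, at least 3.71-fold lower (adjusted p = 0.016).

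The genes called between genotypes in water and in salt overlapped. These comparisons share no array, but they share each gene's estimate of spread, and slide is confounded with genotype in both. Fisher's test also treats genes as independent, which they are not. Of genes higher in the overexpressor 1015 were called in both, where independent lists would share 332 (Fisher's exact test, one-sided, p = 3.4e-319). Of genes lower 965 were called in both, where 375 would be shared (exact p = 1.5e-223). Opposite calls were fewer than independent lists would share. They numbered 47 that were higher in water and lower in salt, where 375 would be shared. Another 243 were lower in water and higher in salt, where 332 would be shared. Across genes the differences correlated with Pearson r = 0.47 and Spearman rho = 0.624. Under the slide block 0 calls were shared, since limma then called 1 and 0 genes. The sum of 1980 shared calls became 4229 without overexpressor water replicate 2, 1038 without overexpressor water replicate 3, 982 without mutant water replicate 1, 1130 without mutant water replicate 2, 1123 without mutant water replicate 3, 506 without overexpressor salt replicate 1, 352 without overexpressor salt replicate 2, 491 without mutant salt replicate 2 and 1296 without mutant salt replicate 3.

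In the overexpressor, stress transcription factors, ethylene genes and jasmonate genes were higher after 3 h of salt than in water. Of the stress factors 12 rose, 0 fell and 16 were not called of 28, with 23 higher and 0 lower adjusted over the list alone and a median of 1.99 (adjusted p = 1.9e-20, but adjusted p = 0.17 with an estimated correlation). DDF1 rose at least 56.4-fold, and CBF1 and CBF2 rose by 4.84 and 4.32 on the log2 scale (adjusted p = 0.0042, 0.016 and 0.02). RRTF1 rose at least 257-fold, DDF2 at least 23-fold and the mannan synthase-like gene CSLA01 at least 16.7-fold (adjusted p = 0.011, 0.005 and 0.0042). ORA47 and the ubiquitin ligase gene PUB19 rose by 6.42 and 5.66 (SE 0.76 and 1.1; adjusted p = 0.0035 and 0.029). Of the ethylene genes 8 rose, 0 fell and 11 were not called of 19, with 9 higher and 0 lower adjusted over the list alone and a median of 1.48 (adjusted p = 2.3e-08, but adjusted p = 0.17 with an estimated correlation). ACS6, ERF11 and ERF105 rose by 3.54, 3.31 and 3.18 (adjusted p = 0.0025, 0.005 and 0.018). Of the jasmonate genes 5 rose, 0 fell and 19 were not called of 24, with 17 higher and 0 lower adjusted over the list alone and a median of 1.47 (adjusted p = 1.6e-13, but adjusted p = 0.17 with an estimated correlation). The jasmonate repressor genes JAZ5 and JAZ7 and the allene oxide cyclase gene AOC3 rose by 3.44, 3.42 and 3.04 (adjusted p = 0.0021, 0.025 and 0.017). A list of 12 touch and wound genes, chosen after the data were seen, had a median of 2.32 here, with 8 called higher and 0 lower. Altogether 666 genes were called, 391 higher and 275 lower, 420 of them at least 2-fold (337 higher and 83 lower). Of all 20406 genes tested, 4687 had groups that did not overlap, where chance gives 10%. Higher genes were 58.7% of the calls, but 46.9% after quantile normalization, 46.6% after normexp correction and 46.8% in the authors' table. With slide as a block 26 genes were called. Within slide 1, where salt replicate 1 met all water replicates, limma called 0 genes with 940 at an unadjusted p under 0.05, and list medians were 2.2 for stress factors, 1.3 for ethylene and 1.71 for jasmonate. The count of 666 became 363 without overexpressor water replicate 1, 2763 without overexpressor water replicate 2, 238 without overexpressor water replicate 3, 254 without overexpressor salt replicate 1, 151 without overexpressor salt replicate 2 and 311 without overexpressor salt replicate 3.

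Of the proline genes in the overexpressor 1 rose, 0 fell and 9 were not called of 10, with 1 higher and 0 lower adjusted over the list alone and a median of 0.335 (adjusted p = 0.016, but adjusted p = 0.17 with an estimated correlation). The gene was P5CS1, which rose by 2.89 (SE 0.47, adjusted p = 0.012). The list call ended without overexpressor water replicate 2 (0.303, adjusted p = 0.17). ABA and dehydration responsive genes were 0 higher, 0 lower and 16 not called of 16 over all genes, but 12 higher and 0 lower adjusted over the list alone, with a median of 1.5 (adjusted p = 1.2e-08, but adjusted p = 0.3 with an estimated correlation); their median within slide 1 was 1.52. Of ABA metabolism and signalling genes 2 rose, 2 fell and 23 were not called of 27, with 5 higher and 4 lower adjusted over the list alone and a median of 0.32 (adjusted p = 0.0039, but adjusted p = 0.3 with an estimated correlation). The phosphatase gene HAI2 rose at least 6.58-fold and CYP707A3 by 3.29, and the ABA receptor gene PYL4 changed by -2.7 (adjusted p = 0.021, 0.0033 and 0.0021). This ABA call ended without overexpressor water replicate 2 (0.253, adjusted p = 0.33). Of glucosinolate genes 2 rose, 0 fell and 17 were not called of 19, with 3 higher and 0 lower adjusted over the list alone and a median of 0.69 (adjusted p = 7.8e-08, but adjusted p = 0.28 with an estimated correlation): UGT74B1 and CYP79B3 rose by 0.69 and 1.48. Of raffinose, starch and sucrose genes 1 rose, 0 fell and 11 were not called of 12, with 3 higher and 0 lower adjusted over the list alone and a median of 0.76 (adjusted p = 0.0026, but adjusted p = 0.28 with an estimated correlation). The sucrose synthase gene SUS3 rose by 1.54, and the list call ended without overexpressor water replicate 2 (0.851, adjusted p = 0.066). Wax and lipid transfer genes were 0 higher, 0 lower and 13 not called of 13, with 0 higher and 0 lower adjusted over the list alone and a median of 0.58 (adjusted p = 0.00025, but adjusted p = 0.28 with an estimated correlation). Flavonoid genes were 1 higher, 0 lower and 19 not called of 20, with 1 higher and 0 lower adjusted over the list alone and a median of 0.535 (adjusted p = 0.0033, but adjusted p = 0.52 with an estimated correlation). The anthocyanin regulator gene PAP1 rose by 2.85, and the list call ended with slide as a block (0.27, adjusted p = 0.063).

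Class III peroxidases in the overexpressor were 0 higher, 0 lower and 45 not called of 45 under salt, with 0 higher and 0 lower adjusted over the list alone and a median of 0.9 (adjusted p = 0.00013, but adjusted p = 0.52 with an estimated correlation), or 0.88 with dim genes at their bound. That call ended with slide as a block (0.137, adjusted p = 0.095) and without overexpressor water replicate 1 (0.3, adjusted p = 0.088). Root markers moved with these groups: they were 0 higher, 0 lower and 13 not called of 13, with 0 higher and 0 lower adjusted over the list alone and a median of 0.85 (adjusted p = 0.04, but adjusted p = 0.67 with an estimated correlation). The root marker call ended with slide as a block (0.443, adjusted p = 0.6), without overexpressor water replicate 1 (0.296, adjusted p = 0.24), without overexpressor water replicate 3 (0.568, adjusted p = 0.1) and without overexpressor salt replicate 3 (0.269, adjusted p = 0.64). In the cell wall list 2 rose, 1 fell and 16 were not called of 19, with 5 higher and 3 lower adjusted over the list alone; XTH22, XTH18 and EXPA5 changed by 2.91, 2.31 and -0.99. The superoxide dismutases were not called (-0.36 to 0.21), nor were the proline genes besides P5CS1 (-1.05 to 0.72). The receptor-like kinase gene CRK30 fell at least 8.22-fold, MIR393b, whose microRNA targets auxin receptors, at least 4.08-fold and SAUR75 at least 3.64-fold (adjusted p = 0.0063, 0.00082 and 0.039). The gibberellin-responsive GASA1 and the auxin-responsive SAUR20 changed by -2.28 and -2.07 (adjusted p = 0.035 and 0.0047).

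In the mutant, ethylene genes and stress transcription factors were lower in the salt arrays than in the water arrays. Of the ethylene genes 0 rose, 8 fell and 11 were not called of 19, with 0 higher and 11 lower adjusted over the list alone and a median of -1.5 (adjusted p = 1.9e-11, but adjusted p = 0.27 with an estimated correlation). ERF6, ERF105 and ERF5 changed by -4.45, -4.08 and -4.01 (SE 0.36, 0.56 and 0.36; adjusted p = 0.0011, 0.0082 and 0.0011). Of the stress factors 0 rose, 7 fell and 21 were not called of 28, with 3 higher and 17 lower adjusted over the list alone and a median of -1.39 (adjusted p = 4.6e-12, but adjusted p = 0.32 with an estimated correlation). DDF1, WRKY40 and ZAT10 changed by -5.36, -3.81 and -3.12 (adjusted p = 0.0096, 0.017 and 0.01). DDF2, ORA47, the mitochondrial carrier gene DIC2 and CYP707A3 were also among the largest decreases, at -5.11, -4.68, -4.2 and -4.16 (adjusted p = 0.019, 0.017, 0.016 and 0.0011). GA2OX7 rose at least 4.58-fold (adjusted p = 0.026), and the cold and ABA responsive KIN2 by 2.01 (adjusted p = 0.044). The auxin-responsive SAUR29, SAUR63, SAUR20 and SAUR27 rose by 1.73, 1.5, 1.47 and 1.35 (adjusted p = 0.0081, 0.023, 0.028 and 0.023). The touch and wound list had a median of -2.35 here, with 0 called higher and 6 lower. The counts were 37 genes higher and 232 lower, 269 in all, 237 of them at least 2-fold (25 higher and 212 lower). Of all 20406 genes tested, 4146 had groups that did not overlap, where chance gives 10%. The slide block left limma calling 0 genes, against 725 at an unadjusted p under 0.05. Within slide 3, where water replicate 3 met all salt replicates, it called 0 genes with 571 at an unadjusted p under 0.05, and list medians were -1.08 for stress factors and -0.64 for ethylene. The count of 269 became 75 without mutant water replicate 1, 81 without mutant water replicate 2, 174 without mutant salt replicate 2 and 146 without mutant salt replicate 3.

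ABA and dehydration responsive genes in the mutant were 1 higher, 0 lower and 15 not called of 16, with 2 higher and 0 lower adjusted over the list alone and a median of 0.93 (adjusted p = 0.0036, but adjusted p = 0.67 with an estimated correlation). The called member was KIN2, at 2.01, and the list call ended without mutant salt replicate 1 (0.328, adjusted p = 0.63). Floral organ markers moved with the mutant's salt comparison: 0 higher, 0 lower and 13 not called of 13, with 0 higher and 0 lower adjusted over the list alone and a median of -0.91 (adjusted p = 0.0088, but adjusted p = 0.67 with an estimated correlation). The floral call in the mutant ended without mutant water replicate 3 (-0.702, adjusted p = 0.069) and without mutant salt replicate 1 (0.0355, adjusted p = 0.63). Heat shock genes were 0 higher, 0 lower and 15 not called of 15, with 0 higher and 0 lower adjusted over the list alone and a median of 0.68 (adjusted p = 0.0095, but adjusted p = 0.67 with an estimated correlation). Their call ended without mutant water replicate 3 (0.742, adjusted p = 0.069), without mutant salt replicate 1 (0.391, adjusted p = 0.16) and without mutant salt replicate 3 (0.58, adjusted p = 0.05). Senescence genes were 0 higher, 0 lower and 11 not called of 11, with 0 higher and 0 lower adjusted over the list alone and a median of 0.48 (adjusted p = 0.037, but adjusted p = 0.67 with an estimated correlation), and the call ended without mutant water replicate 3 (0.534, adjusted p = 0.13) and without mutant salt replicate 1 (0.234, adjusted p = 0.42). Of expansins and XTHs 0 rose, 2 fell and 17 were not called of 19, with 0 higher and 2 lower adjusted over the list alone and a median of -0.11 (adjusted p = 0.0088, but adjusted p = 0.62 with an estimated correlation); XTH22 and XTH18 changed by -3.68 and -2.86. No proline gene was called in the mutant (-0.52 to 0.78), with P5CS1 at 0.31 (SE 0.47). No superoxide dismutase was called either (-0.31 to 0.24).

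**Figure D2:**
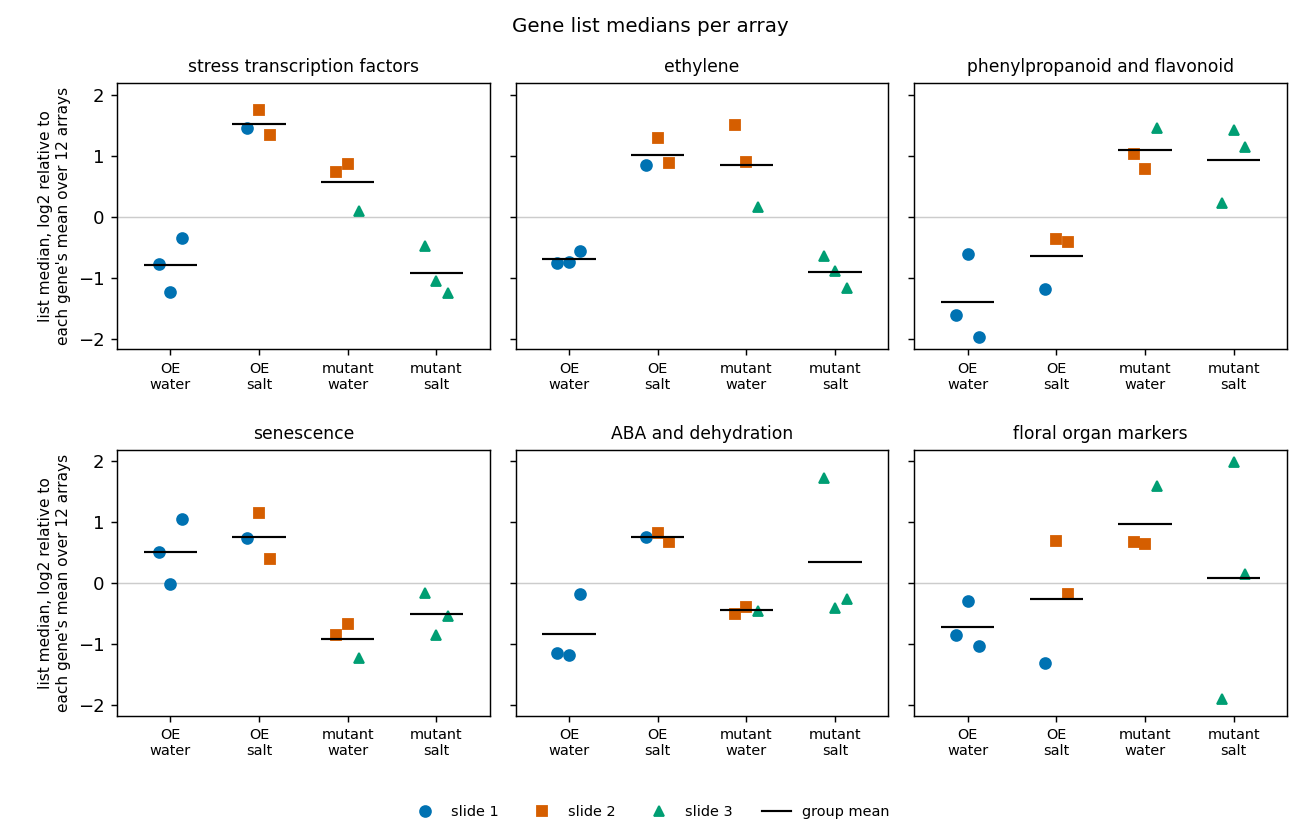
Medians of 6 gene lists on each of the 12 arrays, as log2 values relative to each gene's mean over all arrays; each point is 1 array, its shape and colour give the slide, and lines are group means. Stress factors lie at 1.34 to 1.75 in the overexpressor in salt and at -1.25 to -0.475 in the mutant in salt, every flavonoid median of the mutant lies above those of the overexpressor, and floral markers range from -1.9 to 1.99 among the 3 mutant salt arrays.

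The salt responses of the genotypes ran in opposite directions for many genes. Of genes called in both, 162 rose in the overexpressor and fell in the mutant, where independent lists would share 4.45 (Fisher's exact test, one-sided, p = 1.3e-235). Another 15 fell in the overexpressor and rose in the mutant, where 0.499 would be shared (exact p = 4.3e-19). These tests treat genes as independent, which they are not. Slide 2 held 2 arrays each of the overexpressor in salt and the mutant in water, and none of the other groups. A shift of that slide alone would also move the salt differences of the genotypes in opposite directions. Such a shift does not enter the contrasts within slide 1 or slide 3. There 100% of the salt calls in the overexpressor (slide 1) and 100% of those in the mutant (slide 3) kept their direction. However, the same arrays made the calls, and each contrast rests on 1 array in an arm. The overlap therefore does not separate slide from opposite salt responses. CP12-3, a regulator of the Calvin cycle, was called higher in both, at 0.58 in the overexpressor and 0.61 in the mutant. PYL4 was called lower in both, at -2.7 and -1.32, as was AT1G72416, at -1.89 and -1.17. Independent lists would share 0.709 genes called higher and 3.13 called lower (exact p = 0.51 and 0.82). CP12-3 and AT1G72416 were chosen after their values were seen. Across genes the responses correlated with Pearson r = -0.261 and Spearman rho = -0.131. The 3 calls in the same direction became 9 without overexpressor water replicate 2, 1 without overexpressor water replicate 3, 0 without mutant water replicate 1, 1 without mutant water replicate 2, 1 without mutant water replicate 3, 1 without overexpressor salt replicate 1 and 0 without overexpressor salt replicate 2. The 177 opposite calls became 115 without overexpressor water replicate 3, 64 without mutant water replicate 1, 66 without mutant water replicate 2, 103 without overexpressor salt replicate 1, 78 without overexpressor salt replicate 2 and 117 without mutant salt replicate 3, and 0 with slide as a block, where limma called 0 genes in the mutant.

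The interaction of genotype and salt, which tests that difference itself, was more positive in the overexpressor for stress regulators. Stress transcription factors were 16 higher, 0 lower and 12 not called of 28, with 21 higher and 0 lower adjusted over the list alone and a median of 3.77 (adjusted p = 3.8e-22, but adjusted p = 0.13 with an estimated correlation). DDF1, CBF1 and CBF2 differed by 11.6, 8.38 and 7.74 (SE 1.1, 1.2 and 1.1, limma adjusted p = 0.00039, 0.0035 and 0.0038). DDF1 was dim in the overexpressor in water, so its value is a fitted one and no bound. Ethylene genes were 9 higher, 0 lower and 10 not called of 19, with 11 higher and 0 lower adjusted over the list alone and a median of 3.23 (adjusted p = 1.2e-11, but adjusted p = 0.13 with an estimated correlation). Jasmonate genes were 6 higher, 0 lower and 18 not called of 24, with 9 higher and 0 lower adjusted over the list alone and a median of 1.38 (adjusted p = 1.8e-08, but adjusted p = 0.49 with an estimated correlation). The most negative named genes included SAUR75, MIR393b and SAUR20 at -4.05, -3.65 and -3.55 (adjusted p = 0.0096, 0.00013 and 0.00071). SAUR75 and MIR393b were dim in the overexpressor in salt, so their sizes and rank are fitted ones as well. The auxin response list had 1 higher, 1 lower and 17 not called of 19, with 1 higher and 2 lower adjusted over the list alone and a median of 0.035 (adjusted p = 0.88). In the ABA metabolism and signalling list, 1 higher, 0 lower and 26 not called of 27 with 3 higher and 2 lower adjusted over the list alone, CYP707A3 differed by 7.45 (adjusted p = 0.00013). P5CS1 differed by 2.58 (SE 0.67, adjusted p = 0.067) and was not called. Proline genes were 0 higher, 0 lower and 10 not called of 10, with 2 higher and 0 lower adjusted over the list alone, and the superoxide dismutases were not called (-0.47 to 0.52). For bHLH112 itself the interaction was 0.2 (SE 0.27, adjusted p = 0.74). In all 780 genes were called, 496 with a more positive and 284 with a more negative response in the overexpressor, 618 of them by at least 2-fold (469 more positive and 149 more negative). The median of all genes was -0.101 in this test and -0.136 after quantile normalization. With slide as a block 77 genes were called, and 100% of the 780 had the same direction. The count of 780 became 2656 without overexpressor water replicate 2, 478 without overexpressor water replicate 3, 431 without mutant water replicate 1, 422 without mutant water replicate 2 and 406 without overexpressor salt replicate 2.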

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

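The slide and label tests of the stress factors and both tests of the floral markers were chosen only after the result was seen. The genes and lists named first stand out because the test of the interaction showed a different salt response in the genotypes. It called 780 genes. List medians of the interaction were 3.77 (adjusted p = 3.8e-22, but adjusted p = 0.13 with an estimated correlation) for stress transcription factors, 3.23 (adjusted p = 1.2e-11, but adjusted p = 0.13 with an estimated correlation) for ethylene and 1.38 (adjusted p = 1.8e-08, but adjusted p = 0.49 with an estimated correlation) for jasmonate. They were 0.43 (adjusted p = 0.0039, but adjusted p = 0.78 with an estimated correlation) for glucosinolate and 0.73 (adjusted p = 0.0039, but adjusted p = 0.73 with an estimated correlation) for wax and lipid transfer genes. In the glucosinolate list MYB51 was called at 2.5, 1 of 19, with 1 higher and 0 lower adjusted over the list alone; in the wax list 0 were called, with 0 higher and 0 lower adjusted over the list alone. The remaining medians were 0.67 (adjusted p = 0.019, but adjusted p = 0.78 with an estimated correlation) for flavonoid genes, 0.59 (adjusted p = 0.013, but adjusted p = 0.78 with an estimated correlation) for class III peroxidases, 0.899 (adjusted p = 0.046, but adjusted p = 0.79 with an estimated correlation) for ABA and dehydration responsive genes and 1.28 (adjusted p = 0.021, but adjusted p = 0.78 with an estimated correlation) for floral organ markers, with 0 members called in each, also adjusted over the list alone. The flavonoid call ended without mutant water replicate 3 (0.54, adjusted p = 0.081) and without mutant salt replicate 1 (0.35, adjusted p = 0.17). The peroxidase call ended with slide as a block (0.14, adjusted p = 0.07), without overexpressor water replicate 1 (-0.0415, adjusted p = 0.28), without mutant water replicate 3 (0.0982, adjusted p = 0.067) and without overexpressor salt replicate 3 (-0.133, adjusted p = 0.1). The floral call ended with slide as a block (0.974, adjusted p = 0.096), without overexpressor water replicate 2 (1.43, adjusted p = 0.12), without mutant water replicate 3 (1.06, adjusted p = 0.073), without overexpressor salt replicate 2 (0.764, adjusted p = 0.13) and without mutant salt replicate 1 (0.207, adjusted p = 0.29). The ABA and dehydration call ended with no filter on dim probes (0.837, adjusted p = 0.082), with slide as a block (0.683, adjusted p = 0.096), without overexpressor water replicate 1 (0.699, adjusted p = 0.05), without overexpressor water replicate 2 (0.731, adjusted p = 0.51), without mutant water replicate 2 (0.913, adjusted p = 0.068), without mutant water replicate 3 (0.888, adjusted p = 0.067), without overexpressor salt replicate 1 (0.828, adjusted p = 0.065), without overexpressor salt replicate 2 (0.885, adjusted p = 0.059), without mutant salt replicate 2 (0.682, adjusted p = 0.31) and without mutant salt replicate 3 (0.394, adjusted p = 0.23), with the values of 0.05 just above the threshold.

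The genes with a more positive salt response in the overexpressor were RRTF1 (15), DDF1 (11.6), DDF2 (11.5), ORA47 (11.1), DIC2 (8.43), CBF1 (8.38), CBF2 (7.74) and ERF6 (7.53), and further ERF105 (7.26), ACS6 (6.86), XTH22 (6.59), JAZ7 (6.16), JAZ8 (6.05), LOX4 (6.04), XTH18 (5.17) and XTH17 (5.02). Those with a more negative one were GA2OX7 (-4.23), SAUR75 (-4.05), MIR393b (-3.65), SAUR20 (-3.55), SAUR63 (-3.47) and SAUR29 (-3.4). For genes that were dim in a group, such as RRTF1, these are fitted log2 values and no bounds. A signal also appeared in probes that map to no single gene and entered no comparison: 730 of 3098 such probes were called between genotypes in water, 354 of them higher. Groups of 3 were too small for a test of single arrays.

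The stress factors' opposite movement under salt was weighed against slide, exchanged labels and handling. Slide cannot be told apart from a real response, because within a slide each salt difference rests on 1 array in an arm, and what its test showed changed with its form: with a spread over genes both medians within a slide lay beyond 0 (2.2, SE 0.26, in the overexpressor and -1.08, SE 0.32, in the mutant), whereas with slide as a term and the spread between arrays 2.23 in the overexpressor did (95% interval 1.19 to 3.28) and -1.02 in the mutant did not (-2.06 to 0.0261). If the mutant labels were exchanged, ABA and dehydration genes would be lower in the arrays labelled salt: their median difference was 0.328 without salt replicate 1 (SE 0.2), 1.54 without replicate 2 and 1.2 without replicate 3, so the higher level rests on replicate 1 and exchanged labels cannot be told apart from a real response. Handling of the plants before harvest may account for it, because 12 touch and wound genes, 0 of them in the other lists and chosen once the touch-induced XTH22 had been seen to move, had a median interaction of 4.75 with 8 called higher. Their medians were -2.1 between genotypes in water, 2.82 in salt, 2.32 for salt in the overexpressor and -2.35 in the mutant; a salt response that depends on the genotype stays open and was not separated from handling.

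The differences between genotypes were weighed against slide, because no slide held both groups of either comparison. Of 86 genes called between genotypes from slides 1 and 3, 70 (81.4%) had the same direction on slide 2, and of all genes 79% did (Pearson r = 0.56 across genes). This argues against slide as the whole cause of the direction, although the slide 2 contrast also differs in treatment. Within slide 2, limma called 3843 genes between the overexpressor in salt and the mutant in water (2 arrays each), while the fits with slide as a block called 1 and 0 between genotypes in water and in salt, so how many genes differ by genotype alone stays open. The genotype itself stays among the open explanations.

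Floral organ markers differed widely between arrays of a group, from -1.9 to 1.99 among the mutant salt arrays. Dim probes are argued against, since the 7 brighter members had a median within-group SD of 1.33, where all genes had 0.281. An unequal share of flower-bearing tissue in the pooled plants may account for the spread: after group means were removed, the markers moved together, with a median correlation of 0.871 of a marker with the mean of the others (12 of 13 above 0.5, the lowest 0.43). The labels give no flowering stage, so no biological explanation was tested. With the floral median as a covariate, an alternative chosen after seeing the data, 3367 genes were called between genotypes in water.

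Other splits of the same arrays were fitted as well. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 7524 genes in water and 3835 in salt between genotypes, with 0 in the highest other split of each, so 1 split in each called as many. In the mutant the salt split called 269 and the highest other 1, again with 1 split at the real count. In the overexpressor 2 splits called as many as the real 666, and the highest other, 1077, set water replicates 1 and 3 and salt replicate 1 against the rest. Those groups have the same make-up of slides as the real ones, as have 2 further splits, which called 0 and 1 genes; with slide as a block the real split called 26. In the mutant the 3 other splits with the real make-up of slides called 0, 1 and 0 genes. For the interaction 3 of 100 splits drawn, the real split among them, called as many as the real 780. Splits that mix the genotypes put the difference between genotypes into the spread, which can lower their counts. The splits that called 4144 and 1206 genes were mixed too, so mixing does not always do so. The share therefore does not settle chance. With slide as a block 77 genes were called, and 100% of the 780 kept their direction while the median SE rose from 0.316 to 0.462. Slide is not settled by the splits either, as no other split has the real make-up of slides. The highest other, 4144, points to a structure of the samples: it exchanged water replicates 1 and 3 between the genotypes and left the salt arrays in place, which sets the difference between genotypes in salt against mixed water groups.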

How the results depend on the processing

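The alternatives with both divergent arrays left out and with the floral covariate were chosen after seeing the data. Leaving out 1 array at a time gave 2924 to 10770 called genes between genotypes in water and 783 to 6339 in salt. It gave 151 to 2763 for salt in the overexpressor, 75 to 336 in the mutant and 406 to 2656 for the interaction. The shared calls ranged from 0 to 9 for the salt responses and 352 to 4229 for the genotype comparisons, opposite salt calls from 64 to 213 and called lists from 39 to 52. bHLH112 kept its direction and call, 3.25 to 3.5 in water and 3.39 to 3.74 in salt. A group left with 2 arrays shared the spread of the other groups. Slide as a block called 1, 0, 26, 0 and 77 genes in these comparisons, left 0 shared salt, 0 shared genotype and 0 opposite calls, and gave bHLH112 3.56 and 3.7. Its construction accounts for much of this, as the median SE between genotypes went from 0.223 to 0.432. Of the 47 called lists 35 kept their direction and call with slide as a block, 9 were no longer called and 3 reversed; 43 lists were called in all. Slide as a block also reversed medians in water to -0.0261 for photosynthesis and 0.178 for floral markers, and in salt to -0.0423 for jasmonate. The peroxidase interaction median reversed to -0.0415 without overexpressor water replicate 1 and -0.133 without salt replicate 3, in a range up to 1.11. The mutant's floral median reversed to 0.0355 without salt replicate 1, in a range down to -1.59. TT19 reversed to 0.645 with only probes well above background on all arrays, as that filter takes its other probe. Only the arrays compared, with fewer arrays to estimate the spread, called 2991 genes in water and 3071 in salt between genotypes. They called 217 for salt in the overexpressor and 39 in the mutant, with 0 shared salt, 846 shared genotype and 24 opposite calls. The cause of the smaller fall in salt was not tested. For the interaction these are all arrays, so no value was added. The shared salt calls were 6 under quantile normalization and in the authors' table, 9 after normexp correction, 5 with the percentile over detected probes and 6 with a variance trend; the cause was not tested. With no filter on dim probes 1269 genotype calls were shared. Without both divergent arrays 11418, 7763, 3508 and 2753 genes were called in water, in salt, for salt in the overexpressor and for the interaction, with 6 shared salt and 5166 shared genotype calls; the cause was not tested. The floral covariate left 3367 in water, 5 shared salt and 1025 shared genotype calls; the cause was not tested. Camera with an estimated correlation called 0 of the 47 lists. The estimates for these lists, from 0.012 for proline to 0.85 for photosynthesis genes, exceeded the preset 0.01, which makes the test stricter. Fry, a rotation test of a list on its own rather than against other genes, was run beside camera. In the interaction its adjusted p was 0.0014 for stress factors, 0.00074 for ethylene and 0.053 for jasmonate. It was 0.31 to 0.65 for the other lists that camera called there. Of named gene results 250 kept their direction and their status as called or not called under quantile normalization, with 4 no longer called. With a variance trend 253 did. With slide as a block 62 did, 169 were no longer called, and 24 that were called in neither fit changed direction. Results called in neither fit count among those kept, so the 62 are not all calls that held. Dim probes limit the fold of genes near background, which is why bounds are given.

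With replicate number as a replicate block, 424 genes were called for salt in the overexpressor; the cause was not tested. Of 18 same-numbered pairs, whose correlations ran from -0.39 to 0.41, 6 correlated above 0.1. Differently numbered pairs were not set beside them, so this does not settle whether the numbers pair the samples.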

Other observations

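Markers of other tissues gave few calls. Between genotypes the root marker MRN1 was called lower in water, too near background for a fold, and was at least 1.28-fold lower in salt, 1 of 13 each; 0 higher and 0 lower adjusted over the list alone in water and 0 higher and 1 lower adjusted over the list alone in salt. The root list had medians of -0.49 and -0.25 (adjusted p = 0.62 and 0.85), or -0.26 in water with dim genes at their bound. Of 8 anther tapetum and pollen coat markers AMS, a tapetum regulator, was at least 4.58-fold lower in water, with 0 higher and 0 lower adjusted over the list alone. That list had medians of -1.4, -0.305, 0.29 and -1.37 in water, in salt, for salt in the overexpressor and for salt in the mutant (adjusted p = 0.3, 0.86, 0.99 and 0.076); the third was -0.082 with dim genes at their bound. Of 3 seed storage genes CRU3, a cruciferin, was higher (1.93) in water, with 1 higher and 0 lower adjusted over the list alone and a median of -1.58 (adjusted p = 0.99). ERD1, AMS, CRU3, MRN1 and the other genes named in this part were chosen after their values were seen.

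ABA and dehydration responsive genes did not differ as a list between genotypes, with medians of -0.4 and 0.65 (adjusted p = 0.53 and 0.16). ERD1, a chloroplast protease regulator, was called higher in water at 1.64, 1 of 16, with 1 higher and 0 lower adjusted over the list alone. The vacuolar exchanger gene NHX2 was higher in salt by 0.83 in the overexpressor, 1 of 21 ion transport genes, with 1 higher and 0 lower adjusted over the list alone. The glutaredoxin gene GRX480 rose by 2.25 there, 1 of 17 defence genes, and its interaction was 3.89. Between genotypes in salt the auxin genes IAA17 and IAA5 differed by -1.13 and -1.91, with 0 higher and 2 lower adjusted over the list alone and a median of -0.53 (adjusted p = 0.27). The cell wall genes XTH22, XTH18 and XTH17 had interactions of 6.59, 5.17 and 5.02, with 5 higher and 1 lower adjusted over the list alone and a median of 0.35 (adjusted p = 0.053). Wax and lipid transfer genes were 0 higher, 0 lower and 13 not called of 13 in water and 0 higher, 0 lower and 13 not called of 13 in salt between genotypes, with medians of -0.56 and 0.58 (adjusted p = 0.41 and 0.056).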
